A study of Mus musculus with 72 samples.

How the data were processed

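CUT&RUN libraries for H3K27me1, H3K27me2 and IgG came from the mouse nucleus accumbens, 72 samples in 21 groups taken from the sample titles. Per the submitters' processing notes, reads were handled with Trim Galore 0.6.5, cutadapt 2.10, Bowtie2 2.4.1, SAMtools 1.10 and MACS2 2.2.6 on the mm10 mouse genome; the notes as used here give no role or order. Differential sites came from diffReps 1.55.4, per the file headers, with windows of 1000 bp, a step of 100 bp, a fragment size of 100 bp and a p limit of 0.0001. Per the file headers, the 4 chronic defeat tables used a G-test, which pools the reads of each group, and the ELS table a negative binomial test, which models the spread between libraries. The names of the 4 defeat tables carry an abbreviation that points to a negative binomial test instead. A G-test rebuilt from the normalised counts came within 0.05 log10 units of the deposited p at 99.2% to 99.9% of their sites, against 6.06% in the ELS table, so the headers were followed. IgG libraries served as background in each table, and the names of the read files record unique alignments with duplicates removed, per the file headers.

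The deposited normalised counts per library are a signal: reads in a site divided by a library constant given in the headers. Multiplying back gave whole reads for 100% of values (within 0.1), but no raw counts are given in a column of their own, so the authors' adjusted p stayed the test of each site, as chosen before the data were examined. The deposited log2 fold changes are stressed over control group means, by the authors. The deposited enrichment is a ratio of group signal over IgG background, by the authors. The p-value and adjusted p-value are the authors', with Benjamini-Hochberg adjustment over 270324, 275586, 48304, 52728 and 1287727 windows per the file headers. The deposited tables hold windows that passed the authors' limit; other windows were not analysed here, so counts of gene list members adjusted over the list alone were not computed, and enrichment over all windows was not tested.

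Samples, alternatives, tests and the 19 gene lists were fixed before the data were examined. The lists were potassium channels, sodium and calcium channels, glutamate receptors, GABA receptors and synthesis, medium spiny neuron identity, synaptic adhesion, axon guidance, cAMP and calcium signalling, Polycomb and H3K27 methylation, developmental transcription factors, glucocorticoid, stress and neurotrophin signalling, immediate early genes, astrocyte, oligodendrocyte, microglia, vascular, and cortical and interneuron markers, ribosomal proteins, and chemosensory receptors. Named genes were chosen by a rule fixed with them. It took the 8 higher and 8 lower genes of smallest adjusted p per table (5 and 5 for H3K27me2), leaving out predicted and unnamed gene symbols and sites with a mean below 10 reads. It added up to 4 members of each list, the first 8 genes sharing a direction in susceptible and ELS tables, and the H3K27 enzyme genes. Genes named for holding most sites, and regions, were chosen after their values were seen.

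Sites past an adjusted p of 0.05 were assigned to promoters (within 1000 bp of a transcription start), gene bodies or intergenic sequence of 21951 protein-coding genes of GENCODE release M21, which uses the files' build. Shares of higher sites carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. Differences in shares between tables used sign flips over chromosomes (two-sided permutation, 100000 resamples). Chromosomes of the same libraries are not separate samples, so the p-values of these flips do not measure the spread between libraries. Overlaps of at least 1 bp were set against 1000 circular shifts within chromosomes (one-sided), shared genes against 10000 gene sets matched on length (one-sided), and list membership against 10000 matched lists (two-sided). These gene sets and lists were not limited to genes with a tested window, without which a gene cannot hold a site. An excess or deficit of genes may therefore reflect where windows were tested. Features and list directions used Fisher's exact test (two-sided) over sites, which treats sites of a gene as independent. Each family was adjusted by Benjamini-Hochberg.

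Tests added after seeing the data were limma 3.58.1 on log2(normalised count + 1) across libraries, adjusted over all windows or over the deposited sites; list directions with genes as units, matched on length or on length and transcript GC; sites without the mitochondrial chromosome; susceptible against resilient lists (also against lists matched on length and GC) and regions of 5 Mb; overlaps with ELS sites called by limma; the GC trend of direction; and simulated and split controls. Fold changes by limma are on that log2 scale, which understates the change of low counts. Means ± SD are over libraries, from the deposited normalised counts. Other software was Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.

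The methods were tested on simulated counts drawn from the real libraries. With Poisson spread the G-test recovered 92.0% and 93.0% of sites changed 1.5-fold at the H3K27me1 depth of the susceptible and resilient tables, 93.5% and 92.5% for H3K27me2, and 22.5% at the ELS depth. With a variance 2 times the mean, 15.44% to 17.31% of unchanged defeat windows had p under 0.05. With 200 changed sites and adjustment over the deposited sites alone, limma recovered 78.7%, 74.7%, 74.7% and 69.3% of 1.5-fold changes in the defeat tables and 17.3% in the ELS table, and 25.3%, 30.7%, 26.7%, 21.3% and 6.7% of 1.3-fold changes. The measured variance over mean within groups had medians of 1.03 to 3.01 in the defeat tables and 0.71 to 0.806 in the ELS table, at sites selected for a difference. Depth limits the ELS table, at 5.0 to 7.78 reads per 1000-bp bin against 10.56 or more in the defeat cohort, and at that depth a 1.5-fold change is mostly missed.

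Alternatives were the sites as deposited, an adjusted p under 0.01, an absolute log2 change of at least 1, a mean of at least 10 reads, joining within 1000 bp, autosomes, enrichment above 1, overlap rules and placement, promoter or nearest-gene assignment, unmatched lists, and each library left out in turn. Each library was left out on the deposited sites, with a G-test rebuilt from the normalised counts for the defeat tables and with limma for the ELS table.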

Results

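Monomethylation and dimethylation of lysine 27 of histone H3 (H3K27me1 and H3K27me2) were profiled in the nucleus accumbens, a ventral striatal region of reward and motivation, from male mice. The assay was CUT&RUN, in which an antibody-directed nuclease releases the DNA around a chromatin mark. The 72 samples fell into 21 groups, with 24 samples each for H3K27me1, H3K27me2 and IgG, the antibody background. One cohort went through chronic social defeat stress and was divided into control, susceptible and resilient mice, with 4 libraries per mark and group. A separate cohort combined rearing (standard or early life stress, ELS) with subthreshold defeat, with 3 libraries per mark and group. The authors' 5 deposited tables of differential sites cover 8 groups and 30 mark libraries; the other groups were not analysed here. Depth differed between cohorts. Per the file headers, the defeat cohort's H3K27me1 libraries averaged 20.57 to 30.39 reads per 1000-bp bin, its H3K27me2 libraries 10.56 (control library 52) to 40.63, and the ELS cohort's H3K27me1 libraries 5.0 to 7.78. The labels do not say that libraries came from separate animals, so p-values across libraries measure only the spread between these samples, which may be technical.

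To see how H3K27me1 differed in mice susceptible to chronic defeat, susceptible and control libraries were compared first. Counted over sites, H3K27me1 was mostly higher in genes of synaptic adhesion, glutamate and GABA receptors and axon guidance, although none of these lists passed with genes as units. Lrrc4c, a postsynaptic adhesion protein that binds netrin-G, had 35 sites, all higher. Its leading site (intron, chromosome 2, 96389301 to 96392100, mm10) held 206 ± 11.3 normalised reads in susceptible and 139 ± 15.9 in control libraries (SD, n = 4 each). That was a log2 change of 0.57 ± 0.13 (SE, limma, unadjusted p = 4.76e-05). The netrin receptor gene Dcc, the only nuclear gene among the 8 higher genes picked by smallest adjusted p, had 26 higher sites and 1 lower, and its first site (intron, chromosome 18, 71741801 to 71745300) held 405 ± 58.8 against 294 ± 39.3 reads. Susceptible library 32, at 317.02 reads, lay apart from the other susceptible libraries at that Dcc site. At the other end stood Trappc10, a vesicle tethering subunit, whose leading exonic site (chromosome 10, 78191701 to 78195300) held 286 ± 31.1 against 397 ± 41.8 reads, a log2 change of -0.47 ± 0.11 (limma, unadjusted p = 0.00014).

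In the authors' deposited table, 12122 sites passed an adjusted p of 0.05 in the susceptible comparison, 6097 higher and 6025 lower. The share of higher sites was 50.3% (95% exact interval 49.4 to 51.2). Changes were small, with a median log2 change of 0.43 at higher and -0.43 at lower sites, and no site reached an absolute log2 change of 1. By the header the authors' test was a G-test, which pools the reads of a group and leaves out the spread between its libraries. Across libraries, limma gave an unadjusted p under 0.05 at 11995 sites, but 0 sites passed once p was adjusted over all 270324 windows the authors tested. Counting unlisted windows as not passing, that adjustment sets the lowest count the test can give. The 11995 sites had been selected for a difference on these same libraries, so that count is no separate support for them. Among the other lower sites, Mxd4, a transcriptional repressor that pairs with Max, held 238 ± 42.2 against 338 ± 28.5 reads at its exonic site. Sympk, a scaffold of messenger RNA 3' end processing, held 214 ± 26.8 against 305 ± 49.8, and Anapc2, a subunit of the anaphase-promoting complex, 217 ± 31.2 against 307 ± 26.3 (SD, n = 4 for each). Of those 8 higher genes, 7 were mitochondrial and shared sites with an enrichment over IgG of only 0.03; at the mt-Cytb site 4010 ± 1140 against 3490 ± 1580 reads did not pass limma (unadjusted p = 0.142). Drg1, at 9210 ± 1110 against 10000 ± 587 reads, was likewise called on very high counts with a log2 change of -0.12 ± 0.11 (limma, unadjusted p = 0.27).

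**Figure D1:**
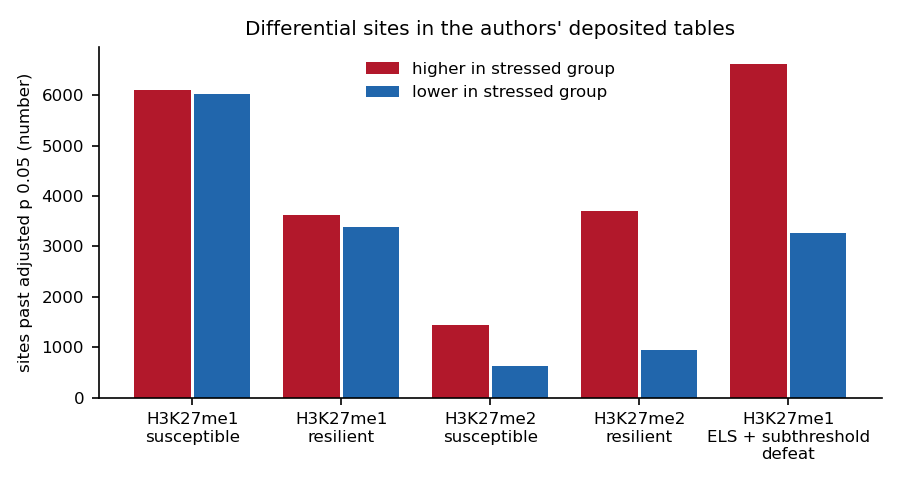
Bars give the number of sites past an adjusted p of 0.05 in each of the 5 deposited tables, red for sites higher and blue for sites lower in the stressed group. The susceptible H3K27me1 table holds 6097 higher and 6025 lower sites, and the resilient H3K27me2 comparison has 3706 and 953.

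**Figure D2:**
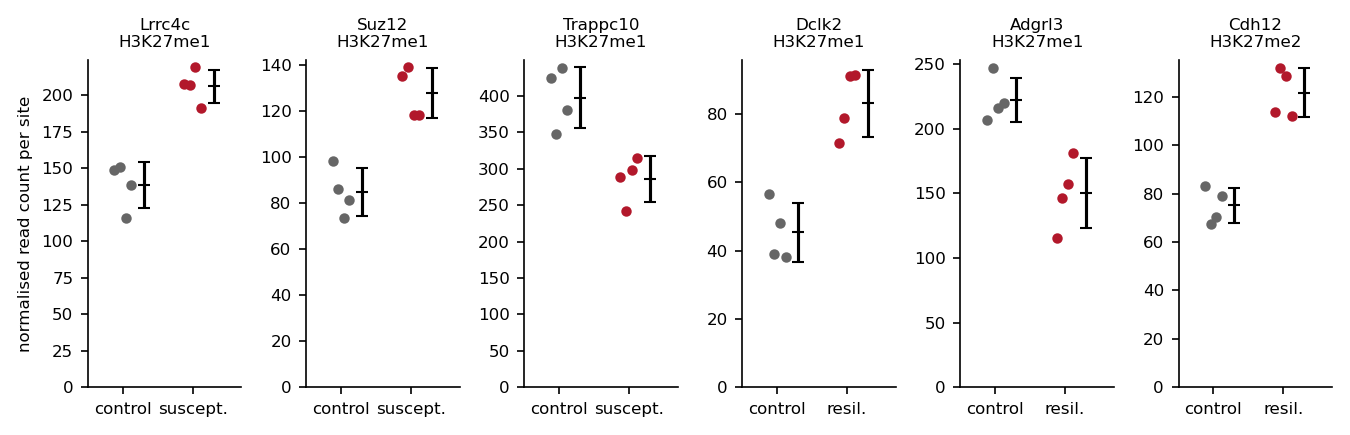
Points give normalised read counts of single libraries at the leading site of 6 genes, grey for control and red for susceptible or resilient libraries, with the mean and SD (n = 4) in black beside them. At Lrrc4c the means are 206 and 139 reads, at Trappc10 286 and 397, and at Dclk2 83.2 and 45.5.

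The genes fell into lists that had been fixed in advance, and neuronal lists stood out for their direction. Synaptic adhesion genes held 476 higher sites of 519 (91.7%, against 48.3% in all other genes; Fisher's exact test, adjusted p = 7.56e-95). Sites lay in 34 of the 42 members on the chromosomes with sites, against 22.1 expected for genes of like length (permutation, adjusted p = 0.00253). By gene, 13 members had only higher sites, 2 only lower and 19 both. Pcdh17, a protocadherin, had 8 higher sites and none lower, with 328 ± 30.6 against 235 ± 20.5 reads at its leading intronic site. Nlgn1, a postsynaptic neuroligin, had 47 higher sites and 1 lower, with 300 ± 38.2 against 222 ± 29.8 reads, and Cntnap5b, a contactin-associated protein, 234 ± 13.7 against 161 ± 4.91 (SD, n = 4 each). Sites of a gene are not independent, and when each gene counted as a unit the mean share of 83.1% did not pass against lists matched on length (permutation, adjusted p = 0.142) or on length and transcript GC (0.55).

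Receptor and guidance genes showed like shares. Glutamate receptor genes held 178 higher sites of 194 (91.8%; Fisher's exact test, adjusted p = 7.06e-35) in 11 members, led by the kainate receptor gene Grik2 with 58 higher sites and 1 lower. Its leading exonic site held 422 ± 61.1 against 314 ± 56.7 reads, and the delta receptor gene Grid1 174 ± 20.5 against 119 ± 8.72 (SD, n = 4). GABA receptor and synthesis genes held 62 of 66 (93.9%; adjusted p = 7.86e-14) in 9 members, with 156 ± 21.4 against 106 ± 8.8 reads at Gabrg1, a subunit of the GABA-A receptor. Axon guidance genes held 124 of 134 (92.5%; adjusted p = 1.5e-25) in 14 members, where the ephrin receptor gene Epha6 had 27 higher sites and none lower and the Slit receptor gene Robo2 had 11 and none. Their leading sites held 262 ± 15.5 against 194 ± 8.62 and 245 ± 10.8 against 182 ± 18.1 reads. With genes as units none of these lists passed when matched on length and GC (permutation, adjusted p = 0.81 for glutamate, 0.55 for GABA and 0.222 for guidance genes).

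Ion channel genes were split by gene. Potassium channel genes held 64 higher sites of 79 (81.0%; Fisher's exact test, adjusted p = 7.07e-08), but 5 members had only higher, 5 only lower and 4 both kinds of sites. Kcnq5, which carries the M current, held 180 ± 6.47 against 127 ± 8.59 reads, whereas Kcnc1, a fast delayed rectifier, held 89.4 ± 6.5 against 132 ± 8.34. Sodium and calcium channel genes held 52 of 70 (74.3%; adjusted p = 0.000153), with the auxiliary subunit gene Cacna2d1 at 204 ± 13.9 against 150 ± 18.3 and the sodium channel gene Scn8a at 99.6 ± 7.04 against 142 ± 9.49 reads (SD, n = 4 each). With genes as units the shares were 58.3% and 56.5%, below the expectation for genes of like length. Genes of cAMP and calcium signalling showed no direction (35 of 59 higher; adjusted p = 0.256), with 7 lower sites and none higher in the protein kinase C gene Prkce, and 7 higher and 7 lower in the phospholipase gene Plcb1. Their leading sites held 101 ± 7.89 against 146 ± 14.9 reads at Prkce and 300 ± 33.5 against 222 ± 9.53 at Plcb1.

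Genes of Polycomb and H3K27 methylation went the other way, with 4 higher sites of 20 (20%, against 50.4% in other genes; Fisher's exact test, adjusted p = 0.0155). Of 12 members with a site, 8 had only lower, 2 only higher and 2 both. Eed, a core subunit of the complex that methylates H3K27, held 77 ± 12.9 against 108 ± 9.65 reads at its leading intronic site and had 2 lower sites. Ezh1, which carries one of its catalytic subunits, held 82.8 ± 20 against 112 ± 18.1. The histone H3K36 methyltransferase genes Ash1l and Nsd2 had 3 and 2 lower sites, with 103 ± 17.3 against 149 ± 1.62 and 149 ± 9.38 against 195 ± 13.2 reads. Suz12, another core subunit, had 1 higher and 1 lower site, the higher (exon, chromosome 11, 79998401 to 79999900) at 128 ± 10.9 against 85.0 ± 10.4 reads (SD, n = 4 each). The call ended without control library 31 (23.5%) and with genes as units (permutation, adjusted p = 0.758 matched on length and 0.55 matched on length and GC).

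Among cell markers, the microglia list had sites in Cx3cr1 alone, the fractalkine receptor gene, where 0 of 6 sites were higher (Fisher's exact test, adjusted p = 0.0298), with 227 ± 24.2 against 289 ± 25.7 reads at the first (SD, n = 4 each). That call ended on leaving out any of susceptible libraries 26 and 29 or any of the 4 control libraries. Medium spiny neuron genes had sites in 3 of 29 members, fewer than the 8.7 expected by length (permutation, adjusted p = 0.0361), and all 6 sites were higher (adjusted p = 0.0555). They included Rarb, a retinoic acid receptor gene, at 123 ± 9.94 against 90.2 ± 16.9, and Foxp2, a forkhead transcription factor gene, at 106 ± 12.4 against 77.4 ± 6.15 reads. Astrocyte genes had 5 of 5 sites higher (adjusted p = 0.1), with 76 ± 7.01 against 52 ± 4.75 at the bicarbonate cotransporter gene Slc4a4. Glucocorticoid, stress and neurotrophin genes had 21 of 33 higher (adjusted p = 0.236) in 5 members with sites of both directions. These included the glucocorticoid receptor gene Nr3c1 (134 ± 19.8 against 97.5 ± 16.8) and the neurotrophin-3 receptor gene Ntrk3 (104 ± 6.99 against 70.2 ± 5.97). Single lower sites lay in an immediate early gene (Nr4a1, 81.7 ± 8.53 against 111 ± 22.3 reads), an oligodendrocyte gene (Myrf, 64.2 ± 8.59 against 88.7 ± 5.39) and a ribosomal protein gene (Rps14, 56.1 ± 20 against 83.2 ± 8.38). No site lay in 60 developmental transcription factor genes (8.92 expected by length; permutation, adjusted p = 0.0019), 16 vascular genes (4.81 expected; 0.0266) or 17 cortical and interneuron genes (4.21 expected; 0.0361). Of 1472 chemosensory receptor genes 6 had a site (114 expected, permutation, adjusted p = 0.0019), with 3 of 8 sites higher (Fisher's exact test, adjusted p = 0.504). The windows tested covered 270.3 Mb, and genes outside them, which cannot hold a site, stayed in the expectation. These deficits may therefore reflect where windows were tested rather than change, as may the excess in synaptic adhesion genes.

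By position, 18 of the susceptible higher sites (0.295%) and 93 of the lower (1.54%) lay within 1000 bp of a transcription start (Fisher's exact test, adjusted p = 2.5e-13). Gene bodies held 89.3% of higher and 83.6% of lower sites (adjusted p = 1.79e-19), and 10.4% and 14.8% were intergenic (adjusted p = 3.84e-13). The genes with most sites were long, led by Csmd3, a gene of a large complement-domain protein, with 93 sites, 92 of them higher, and by the adhesion genes Lsamp (51, 50 higher) and Cadm2 (54, 49 higher). Direction ran with base composition, a property examined after the direction of the lists had been seen. In the lowest of 5 GC classes of genes (transcript GC up to 42.4%), 79.8% of 2770 sites were higher (95% exact interval 78.2 to 81.3), and in the highest (from 55.1%) 7.95% of 1044 sites (6.38 to 9.76). Per gene, the share fell by 55.2 percentage points from the low to the high class over 19 chromosomes, in 19 of 19 (permutation of signs, p = 1e-05, the smallest it can give). Chromosomes of the same libraries are not separate samples, so this p does not measure the spread between libraries. The drop was in each of the 4 susceptible libraries, with differences in log2 change of -0.67, -0.84, -0.37 and -0.60 between sites of high-GC and of low-GC genes, against -0.15 to 0.18 in the control libraries. These sites had been selected for a difference between these same libraries, and the control mean was the reference. The likeness of the libraries is therefore no separate support for the trend.

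**Figure D3:**
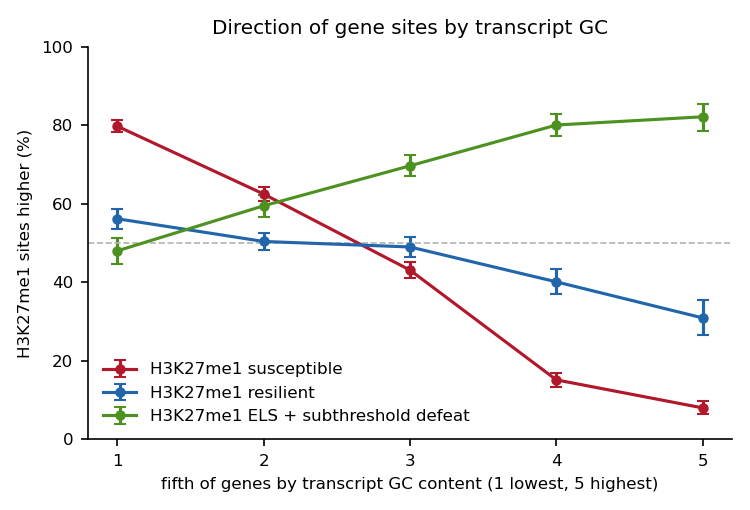
Points give the percent of H3K27me1 gene sites that were higher in the stressed group, by class of transcript GC content (class 1 lowest, class 5 highest), with 95% exact intervals. The share falls from 79.8% to 7.95% in susceptible and from 56.2% to 30.9% in resilient libraries, and it climbs from 48% to 82.2% in the ELS comparison.

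The resilient libraries were set against the same controls to see what H3K27me1 did in mice that went through defeat without the susceptible outcome. Dclk2, a doublecortin-like kinase gene, had the largest log2 change of the 8 leading higher genes. Its intronic site (chromosome 3, 86857501 to 86858600) held 83.2 ± 9.82 against 45.5 ± 8.63 reads (SD, n = 4 each), a log2 change of 0.87 ± 0.16 (limma, unadjusted p = 1.61e-06). Arap2, an Arf GTPase-activating protein gene, held 322 ± 35.4 against 237 ± 36.5, and Ppfia2, a presynaptic liprin gene, 105 ± 10.5 against 63.4 ± 3.47. Lower sites were led by Adgrl3, a latrophilin adhesion receptor gene (150 ± 27.1 against 222 ± 17.2, with 8 lower sites and 5 higher), Rb1cc1, which starts autophagy (234 ± 23.7 against 320 ± 27.9), Snrpc of the U1 splicing particle (206 ± 20.7 against 284 ± 18.4) and the striatin gene Strn3 (187 ± 9.13 against 261 ± 2.79). In the authors' deposited table, a total of 7005 sites passed, 3619 higher and 3386 lower (51.7%, 95% exact interval 50.5 to 52.8). With limma 6988 sites had an unadjusted p under 0.05 and 0 passed after adjustment over 275586 windows. The Chl1 site, ranked first among lower genes by the authors' test, held 20700 ± 1990 against 21600 ± 2050 reads and had a limma p of 0.507.

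Of the neuronal lists in the resilient comparison, 5 leaned to higher sites past the threshold. Synaptic adhesion genes held 163 of 214 (76.2%, against 47.6% in other genes; Fisher's exact test, adjusted p = 8.6e-16) in 31 of 42 members (19.9 expected by length; permutation, adjusted p = 0.0019). Cntnap5a held 225 ± 16.9 against 164 ± 20.7 reads, Cntnap2, a neurexin-family gene, 166 ± 26.2 against 118 ± 12.9, and the cadherin gene Cdh8 150 ± 13.4 against 105 ± 11.1 (SD, n = 4 each). Potassium channel (36 of 50; adjusted p = 0.00305), glutamate receptor (49 of 73; 0.00367), GABA (22 of 29; 0.00946) and axon guidance genes (48 of 67; 0.000777) leaned the same way. Examples were the GABA-A subunit gene Gabrb1 (161 ± 9.33 against 113 ± 9.31) and the Slit receptor gene Robo1 (203 ± 11.4 against 145 ± 23.5). Sodium and calcium channel (23 of 39; adjusted p = 0.239), cAMP and calcium signalling (34 of 56; 0.131) and medium spiny neuron genes (7 of 9; 0.145) did not pass. With genes as units none of the 5 lists passed (permutation, adjusted p = 0.446 matched on length and 0.549 matched on length and GC, the same for each), and the glutamate share of 54.1% was then below the 63.9% expected by length. The potassium, GABA and guidance calls ended without control library 31 (65%, 73.9% and 64.6%). Resilient library 36 also ended the potassium (65.8%) and GABA (72%) calls, and library 30 the GABA call (68.4%).

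Stress genes had 12 of 15 sites higher in resilient libraries (80%; Fisher's exact test, adjusted p = 0.0339), with Nr3c1 at 111 ± 16.4 against 84.3 ± 12.6 reads and the glucocorticoid-induced kinase gene Sgk1 lower at its first site, 114 ± 10.9 against 158 ± 5.96 (SD, n = 4 each). That call was lost without any one of the 4 resilient libraries or of control libraries 31 and 34, at shares of 70% to 76.9%. Polycomb genes had a site in 11 of 25 members (5.11 expected by length; permutation, adjusted p = 0.037), with no direction (7 of 22 higher; Fisher's exact test, adjusted p = 0.178). Ezh2, the other catalytic subunit gene, had 2 higher sites (166 ± 15.8 against 124 ± 16.8), Suz12 1 higher and 2 lower (183 ± 17.8 against 137 ± 25.7 at the higher), and Eed 2 lower (74 ± 13.5 against 101 ± 3.58). Aebp2, an accessory subunit gene, had 2 lower (122 ± 8.93 against 163 ± 7.95). Chemosensory receptor genes had sites in 8 of 1472 members (63.7 expected; permutation, adjusted p = 0.0019), and all 12 sites were higher (adjusted p = 0.000777; with genes as units 0.0018). All 8 genes lie on chromosome 7, such as Vmn1r73 (80.4 ± 8.61 against 53.6 ± 14.9) and Vmn1r139 (95.1 ± 8.33 against 67.9 ± 14.6), so that they are not independent of each other. Intergenic sites were 18.6% of higher and 8.92% of lower sites (Fisher's exact test, adjusted p = 3.48e-31), and gene bodies held 80.5% and 90.0% (7.63e-29), the opposite order from the susceptible sites. Promoters did not differ (33 and 36 sites; adjusted p = 0.547).

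Susceptible and resilient libraries were then compared through their sites, to ask where the outcomes of the same stress shared H3K27me1 changes. Of the susceptible higher sites 719 overlapped resilient higher sites, and of the lower sites 879 overlapped lower sites, against 24.9 and 21.3 in shifted positions (permutation, adjusted p = 0.00333 each, from the smallest raw p the shifts can give) and 81.6 and 75.5 for independent lists. Sites of opposite direction overlapped 22 times (susceptible higher, permutation, adjusted p = 0.713) and 38 times (susceptible lower, 0.0213). Both counts lie below the 76.4 and 80.7 for independent lists. The comparisons share their 4 controls, so chance in the controls gives some shared sites. Simulated unchanged groups at the median spread gave 71 shared sites of one direction, 7.69% of the first group's calls, and 0 opposite; at the upper quartile of spread they gave 1115 (15.0%). Observed at the same limit were 1378 of one direction, 12.3% of susceptible calls, and 44 opposite. With 2 controls in each comparison, 122.7 sites (2.77%) were shared in direction and 12.17 were opposite, as means over 6 splits. The splits re-tested sites already selected with all 4 shared controls, so they do not remove the effect of sharing. By gene, 895 genes were shared among higher (412 expected by length, 143 for independent lists) and 1433 among lower genes (542 and 356; permutation, adjusted p = 0.000333 each).

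The share of higher sites did not differ between susceptible and resilient H3K27me1 tables (-1.75 percentage points over chromosomes; permutation of signs, adjusted p = 0.662). Among 8 gene lists, 1 did, in tests chosen after the tables had been seen. In 29 synaptic adhesion genes with sites in both tables, the mean share was 85.4% in susceptible and 65.1% in resilient libraries, a difference of 20.3 points with 18 genes above 0 and 7 below (permutation of signs, adjusted p = 0.00648). The 10 glutamate receptor genes differed by 27.9 points without passing (permutation, adjusted p = 0.0624), and the other 6 lists by -4.4 to 13.5 points (adjusted p = 0.406 to 1). Set against lists of like length, or of like length and GC, the adhesion difference did not pass either (11 and 13.6 points expected; permutation, unadjusted p = 0.168 and 0.275). Single regions also differed. The strongest regional difference lay on chromosome 7 from 20000001 to 25000000, which holds 144 protein-coding genes, 65 of them vomeronasal type 1 receptor genes. There 19 of 110 susceptible sites (17.3%) and 105 of 116 resilient sites (90.5%) were higher (Fisher's exact test over sites, adjusted p = 4.81e-29). Mean log2 changes of single libraries over these sites were -0.45 to -0.15 in the 4 susceptible and 0.22 to 0.40 in the 4 resilient libraries. Chemosensory receptor genes held only 8 susceptible and 12 resilient sites on all chromosomes, so most sites of the region lay outside them.

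**Figure D4:**
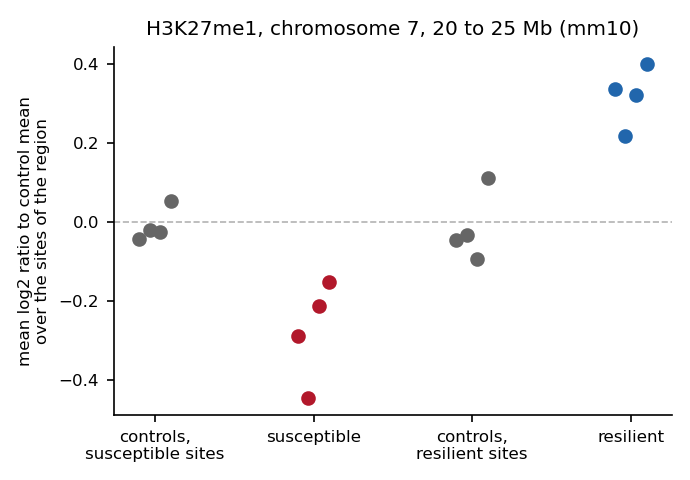
Points give, for single H3K27me1 libraries, the mean log2 ratio to the control mean over all sites of the chromosome 7 region from 20 to 25 Mb (mm10), grey for the controls, red for susceptible and blue for resilient libraries (4 each). Susceptible libraries lie at -0.45 to -0.15 and resilient libraries at 0.22 to 0.40, on sites selected for a difference from the same controls.

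H3K27me2 was compared in the same cohort. In susceptible libraries the leading genes included Ptprc, the leukocyte antigen CD45 gene (118 ± 9.94 against 72.7 ± 29.4 reads; exon, chromosome 1, 138077101 to 138078600) and Themis, of T cell selection (82.5 ± 6.54 against 51.6 ± 12.1). Gpc5, a glypican gene on the astrocyte list with 7 of 8 sites higher, held 159 ± 11.7 against 114 ± 17.8, and Cntnap5b 112 ± 6.23 against 78.6 ± 14.1 (SD, n = 4 each). In resilient libraries they included Col5a2, a fibrillar collagen gene (218 ± 12.3 against 147 ± 13.0 at an intronic site, chromosome 1, 45470101 to 45472500), the tolloid-like protease gene Tll1 (127 ± 1.89 against 79.2 ± 9.73) and the cadherin gene Cdh12 (122 ± 10.2 against 75.1 ± 7.26). Naaladl2 (99.4 ± 11.7 against 56.7 ± 20.9), Cntnap5b (106 ± 10.1 against 72.9 ± 18.7) and the calcium-activated potassium channel gene Kcnn2 (137 ± 9.73 against 95.2 ± 25.2) were also higher. Lower calls in susceptible libraries were led by mitochondrial sites and by Tmem267, a site of high counts with less signal than IgG (2680 ± 213 against 3240 ± 412). The first lower gene in resilient libraries was Smo, also below IgG (226 ± 43.7 against 326 ± 157). Neither passed limma (unadjusted p = 0.141 and 0.108).

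In the authors' deposited tables, a total of 2075 H3K27me2 sites passed in susceptible and 4659 in resilient libraries. Higher sites were 1440 of the first (69.4%, 95% exact interval 67.4 to 71.4) and 3706 of the second (79.5%, 78.4 to 80.7), and the shares differed by -8.88 percentage points over 18 chromosomes, 1 of them above 0 (permutation of signs, adjusted p = 0.00152). The share in H3K27me1 was below that in H3K27me2, with a mean difference over chromosomes of -17.97 points in resilient (51.7% against 79.5% of all sites; adjusted p = 0.0231) and -7.83 in susceptible libraries (50.3% against 69.4%; adjusted p = 0.0787, under 0.05 without susceptible library 53 or 59 or control library 55). Chromosomes counted alike in these means, although chromosomes 7, 9, 17 and 19 held only 2, 7, 7 and 1 susceptible H3K27me2 sites. A mean over chromosomes can therefore lie far from the difference over all sites. With limma 1946 and 4459 sites had an unadjusted p under 0.05 and 0 in each passed over all windows. Without the shallow control library 52 the susceptible count fell to 1258. Most sites were intergenic, 88.7% in susceptible and 90.4% in resilient libraries. Resilient higher sites were more often intergenic (92.4% against 82.8% of lower sites; Fisher's exact test, adjusted p = 1.47e-16) and less often in gene bodies (6.85% against 14.6%; 1.69e-12) or promoters (0.756% against 2.62%; 2.92e-05). Susceptible sites differed in the same directions without passing (adjusted p = 0.0567 to 0.259). Without control library 52 the gene body and intergenic differences passed, and without susceptible library 53 the promoter and intergenic ones. Of the lists, synaptic adhesion genes had 11 of 11 sites higher in susceptible (Fisher's exact test, adjusted p = 0.0222, lost without susceptible library 53 or 59 or control library 55) and 18 of 21 in resilient libraries (adjusted p = 0.143).

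H3K27me2 calls of the susceptible and resilient libraries overlapped at 229 higher and 177 lower sites, against 7.8 and 0.816 in shifted positions (permutation, adjusted p = 0.00333 each) and 110 and 12.5 for independent lists. Of shared sites at the same limit 365 had one direction, 18.7% of susceptible calls, and 10 the opposite. Simulated unchanged groups on the same controls gave 19 (6.79%) at the median and 347 (17.5%) at the upper quartile of spread. All simulated groups had the same spread, averaged over stressed and control sides. The measured median variance over mean was 2.73 and 3.01 in control libraries but 1.2 and 1.03 in susceptible and resilient libraries. The simulation may therefore understate the sites shared through the controls. Splitting the controls left 39.67 (5.11%) in one direction and 8.333 opposite, again among sites already selected with all the shared controls. The marks overlapped little in susceptible libraries, with 1 site higher in both (10.1 in shifted positions; permutation, adjusted p = 1) and 21 lower in both (3.55; 0.00333). Values for independent lists (182 and 79.2) took every H3K27me1 site to lie in the 48304 H3K27me2 windows. H3K27me1 sites came from 270324 windows, so these values are too high to serve as a reference. Shifted positions were not limited to tested windows, so whether the lower sites overlap more than chance stays open. The number of genes shared by both marks did not pass against that expected by length (18 higher against 31.2; 22 lower against 16.6; permutation, adjusted p = 1 and 0.128).

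In the ELS cohort, mice with ELS and subthreshold defeat were compared with standard-reared controls, so that rearing and defeat changed together. Higher H3K27me1 was led by Taf4, a subunit of the general transcription factor TFIID, whose exonic site (chromosome 2, 179920501 to 179922200) held 151 ± 10.5 against 90.5 ± 12.5 reads (SD, n = 3 each), a log2 change of 0.74 ± 0.13 (limma, unadjusted p = 6.42e-08). Egln1, the oxygen-sensing prolyl hydroxylase gene, held 156 ± 10.5 against 106 ± 10.9. The transcription factor gene Sp4 (92.1 ± 6.97 against 151 ± 11.8), Adgrl3 (91.3 ± 6.57 against 147 ± 6.64, 6 lower sites and none higher) and the H3K36 methyltransferase gene Nsd1 (86.2 ± 2.16 against 133 ± 10.4, 4 lower sites) led the lower sites. In the authors' deposited table, from a negative binomial test, 9893 sites passed, 6626 higher and 3267 lower (67%, 95% exact interval 66 to 67.9). Median log2 changes were 0.98 and -0.97, and limma called 9802 sites with p adjusted over all windows. Limma was run only on sites already selected on the same libraries, where the median variance over mean within groups was 0.71 to 0.806. The limma count is therefore no separate support for these sites. Signal was near background, with a median enrichment over IgG of 1.3 in the higher group against 3.32 in the susceptible table, and 22.1% of sites were below IgG. Recounted with limma on 5 libraries, the share of higher sites ranged from 51.9% without ELS library 48 to 79.9% without control library 45. The number of sites ranged from 1294 without control library 37 through 3959 (without control 41), 4332 (control 45), 4772 (ELS library 48) and 5709 (ELS library 44) to 5806 (ELS library 40), against 9802 with limma on all 6.

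In the ELS comparison, synaptic adhesion was the only neuronal list whose share of higher sites differed from that of other genes past the threshold. Its genes held 75 higher sites of 161 (46.6%, against 66.6% in other genes; Fisher's exact test, adjusted p = 6.65e-06) in 39 of 46 members (30.2 expected by length; permutation, adjusted p = 0.0209). Pcdh9, a protocadherin gene, held 35.1 ± 5.15 against 67.5 ± 1.94 reads and Cntnap2 48.2 ± 9.76 against 88.2 ± 6.19, whereas Tenm2, a teneurin gene, held 54.5 ± 2.79 against 25.2 ± 5.4 (SD, n = 3 each). With genes as units the share of 49.8% did not pass (permutation, adjusted p = 0.066 matched on length, 0.348 with GC), and the share over sites was 66.7% without control library 37. Polycomb genes held 2 higher sites of 10 (20%; Fisher's exact test, adjusted p = 0.0314), 1 of them in Ezh2 (72.5 ± 3.59 against 43.4 ± 5.65), a call lost on leaving out any 1 of the 6 libraries. No other list passed against other genes. The other neuronal lists held more higher than lower sites, with 26 of 47 higher for glutamate receptor, 9 of 17 for GABA, 26 of 43 for potassium channel, 19 of 29 for sodium and calcium channel, 38 of 61 for axon guidance, 42 of 56 for cAMP and calcium and 15 of 24 for medium spiny neuron genes. Without single libraries, shares fell as low as 30.8% for glutamate receptor, 33.3% for GABA, 47.6% for potassium channel, 45.5% for axon guidance and 44.4% for medium spiny neuron genes. Sodium and calcium channel genes did not fall below 50%, nor cAMP and calcium genes below 70.6%. Single sites in these lists went both ways, lower at the metabotropic receptor gene Grm7 (107 ± 8.4 against 177 ± 7.45) and the cAMP response factor gene Creb1 (91.6 ± 11.3 against 129 ± 9.95), and higher at the kainate receptor gene Grik4 (60.1 ± 7.61 against 26.6 ± 8.69) and the striatal phosphodiesterase gene Pde10a (35.9 ± 0.68 against 16.9 ± 0.956). The immediate early genes Egr1 (28.8 ± 3.57 against 13.9 ± 4.11) and Dusp1 (16.5 ± 2.25 against 32.9 ± 2.45) went apart, and both sites were below IgG. Promoters held 2.87% of higher and 1.5% of lower sites (Fisher's exact test, adjusted p = 3.23e-05, lost without control library 37). Gene bodies held 41.8% and 45.8% (adjusted p = 0.000218) and intergenic sequence 55.4% and 52.7% (0.0164). The gene body and intergenic order turned without ELS library 48 or control library 37, and the intergenic order also without ELS library 44. The gene body difference did not pass without ELS library 44, nor the intergenic one without ELS library 40.

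To ask whether the susceptible and ELS cohorts changed at the same places, their sites were overlapped; these cohorts share no library. Sites higher in susceptible libraries overlapped ELS higher sites 8 times (38.6 in shifted positions; permutation, adjusted p = 1) and ELS lower sites 60 times (16.6; 0.00333). Lower susceptible sites overlapped ELS lower sites 29 times (16.5; 0.0213) and higher ones 33 times (36.9; 1). Values for independent lists were 149, 73.7, 72.8 and 148, but these took every ELS site to lie in the 270324 susceptible windows. ELS sites came from 1287727 windows, so these values are too high to serve as a reference. Shifted positions were not limited to tested windows, so chance overlap within the windows tested in both was not measured. With ELS sites called by limma on all 6 libraries the 4 overlap counts were 7, 56, 13 and 22. By limma without control library 37 they were 0, 3, 2 and 1, where 1294 ELS sites were left. By gene, 381 genes were lower in both (305 expected by length; permutation, adjusted p = 0.000333) and 429 higher in both (504; adjusted p = 1). Ncoa6, a nuclear receptor coactivator gene, had overlapping exonic sites on chromosome 2, at 121 ± 10.1 against 164 ± 4.99 reads in the susceptible comparison (155417601 to 155419300, SD, n = 4) and 90.7 ± 8.17 against 136 ± 10.7 in the ELS comparison (155418601 to 155419900, SD, n = 3). Mbd5, a methyl-CpG-binding domain gene, was higher in both, at 331 ± 18.4 against 254 ± 37.4 and 175 ± 12.7 against 136 ± 9.55 reads. Among the sites picked by the rule for named genes, groups did not overlap at 46 of 74 (susceptible H3K27me1), 48 of 61 (resilient H3K27me1), 11 of 21 and 17 of 26 (H3K27me2), where chance gives 2.86%, and at 77 of 79 ELS sites, where chance gives 10%. These sites had been selected for their difference.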

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

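Tests chosen after the result was seen were the limma counts and their simulation, the splits of libraries, the GC content tests, the list and region contrasts between susceptible and resilient libraries and the reading of the ELS signal test; the length, length with GC, single library and ELS signal tests were written before their results.

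In susceptible libraries the sites of synaptic adhesion genes were mostly higher (476 of 519), and the mean share per gene exceeded that of resilient libraries by 20.3 percentage points over 29 genes (permutation of signs, adjusted p = 0.00648). Lists of like length and GC differed by 13.6 points on average between these libraries and reached that difference (permutation p = 0.275). Lists of genes of the same length reached the mean share of 83.1% rarely (permutation p = 0.031, unadjusted). That met the bound written beforehand, but the bound was wrong, since the list was picked among several; adjusted over lists p was 0.142, so gene length stays open. Leaving out each library in turn kept the mean log2 change over genes positive, which met the bound written against a single library. The mean was 0.277 ± 0.044 (SE over genes) without susceptible library 29, the lowest, and 0.313 ± 0.045 with all. The sites had been selected for a difference with all these libraries, which favours that outcome. It therefore argues only against a single library carrying the mean at these selected sites. Lists matched on both length and transcript GC reached the share (permutation p = 0.168), so base composition could account for the direction of this list, as could any process that acts by GC content, and a response specific to adhesion genes is not needed. A biological response to defeat remains open and untested, because GC content and outcome go together in these libraries.

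ELS sites went against susceptible sites at loci that were higher in susceptible libraries, where 60 sites met ELS lower sites (16.6 in shifted positions) and 8 met ELS higher sites (38.6). Loci lower in susceptible libraries did not show this, since 29 sites met ELS lower sites (16.5; permutation, adjusted p = 0.0213) and 33 met ELS higher sites (36.9; adjusted p = 1). With ELS sites called by limma the 60 became 56 on all 6 libraries and 3 without control library 37, where 1294 ELS sites were left, and the 29 became 13 and 2. Of 126 shared loci 94 (74.6%) lay in genes with a GC value, too few for a firm test. Among these, 70 were opposite, against 59 when shuffled within GC classes (permutation p = 0.00296), so GC may contribute without being shown to cover the pattern. Lower signal over IgG in the ELS libraries was to have been argued against if defeat-cohort controls had no more enrichment at ELS-lower than at ELS-higher loci. That was met (median difference -0.33), but the bound was wrong, because the loci had been selected partly for low defeat controls. Loci of the resilient comparison were included with the susceptible ones, 118 ELS-lower and 67 ELS-higher sites in all. At these sites the mean of both groups differed by 0.0225 (one-sided permutation p = 0.472), so the explanation and an opposite response cannot be told apart.

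The number of defeat sites rests on a test that pools reads. Simulated unchanged H3K27me1 groups gave 923 calls by that pooled test at the median and 7443 at the upper quartile of spread, and H3K27me2 groups 280 and 1987. Limma across libraries called 0 sites of the 4 defeat tables over the same windows (11995, 6988, 1946 and 4459 at an unadjusted p under 0.05). With each deposited site changed 1.3-fold in simulated counts, the same adjustment called 3347, 1318, 311 and 1105 sites at a variance 2 times the mean and 1190, 206, 86 and 405 at 3 times. Spread between libraries may therefore inflate the deposited counts, by an amount the tables do not give. Real changes smaller than the deposited folds could also give 0 calls, which was not simulated, and stay open. The real grouping gave 656 sites at a limma p under 0.001 in the susceptible H3K27me1 table (highest other split 134; 1 of 35 splits as large), 455 in the resilient (5; 1 of 35), 9 and 85 in the H3K27me2 tables (9 and 15; 2 and 1 of 35) and 10016 in the ELS table (9; 1 of 10). As the sites had been picked on the real grouping, these splits decide nothing about chance, and the ELS design has too few splits for a share under 0.05.

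Among 152 groups of 4 values tested for a library far from the others, 3 had one, fewer than the 1 in 20 that chance gives. Susceptible library 32 held 317.02 reads at the Dcc site, against 426.76 to 437.98 in the others. Resilient library 30 held 67.61 reads at the Vmn1r73 site, against 83.3 to 85.98, and also had the lowest depth of its group (21.29 reads per 1000-bp bin).

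The share of higher H3K27me2 sites differed between susceptible and resilient libraries by -8.88 percentage points (permutation, adjusted p = 0.00152). The difference in direction between high-GC and low-GC genes differed by -39.2 points between susceptible and resilient libraries (permutation of signs over 18 chromosomes, 18 of 18 below 0, p = 1e-05). Between the susceptible and ELS comparisons it differed by -88.5 points (permutation of signs, 19 of 19 below 0, p = 1e-05). This is the smallest p that the permutations can give. These tests over chromosomes, that of H3K27me2 included, do not measure the spread between libraries. Of 106 regions of 5 Mb with at least 20 sites in each table, 35 differed in their share of higher H3K27me1 sites between susceptible and resilient libraries (Fisher's exact test over sites, adjusted p under 0.05), and in 14 of these the direction was opposite.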

How the results depend on the processing

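Comparisons with limma (ELS overlaps on all 6 libraries included), with genes as units and without the mitochondrial chromosome were chosen after seeing the data; the other alternatives were planned. Of 893 values of main results under alternatives, 734 were counted as unchanged. These kept their side of the threshold, and their direction where they passed, or, without a test, stayed within a fixed ratio of the main value. No paired analysis was made, because each library has its own number and the sample titles give no pairing. Whether libraries of different groups were processed in matched sets is unknown. Depth is one limit of the ELS table, and the cause of a change was not tested unless stated.

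Requiring an absolute log2 change of 1 left 0 susceptible H3K27me1, 0 resilient H3K27me1, 0 susceptible H3K27me2, 1 resilient H3K27me2 and 4528 ELS sites, and an adjusted p under 0.01 left 5007 ELS sites. Limma adjusted over all windows called 0 sites in each of the 4 defeat tables (11995, 6988, 1946 and 4459 at an unadjusted p under 0.05). Adjusted over the deposited sites it called 11993, 6988, 1930 and 4453. The deposited sites had been selected for a difference on the same libraries. Counts adjusted over them alone are therefore no separate support for these sites. Leaving out libraries gave 1258 (without control 52, the shallowest) to 2047 susceptible H3K27me2 sites and 1294 to 5806 ELS sites. The share of higher susceptible sites in H3K27me1 minus H3K27me2 ranged from -11.29 to -6.38 points, and passed without H3K27me2 susceptible libraries 53 (-10.28) and 59 (-10.15) or control 55 (-11.29).

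For overlaps, counting sites within 1000 bp as shared gave 92 susceptible higher and resilient lower pairs, which then passed; susceptible lower and resilient higher pairs were 0 with a reciprocal overlap of 50% and 34 at an adjusted p under 0.01, which did not. Without single libraries these pairs ranged from 14 (without resilient 27) to 22 and from 24 (without control 28) to 37. Susceptible H3K27me1 and H3K27me2 overlaps ranged from 0 to 1 (both higher), 11 to 21 (both lower; 11 without H3K27me1 susceptible 29, 12 without H3K27me2 control 55), 0 to 6 (higher and lower; 0 without H3K27me1 control 25) and 0 to 2 (lower and higher). Susceptible and ELS overlaps ranged from 0 to 8 (both higher), 2 to 29 (both lower), 3 to 59 (higher and lower) and 1 to 33 (lower and higher), lowest without ELS control 37 each time, where ELS sites were called by limma and were few. Limma on all 6 ELS libraries gave 13 sites lower in both.

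For features, higher minus lower shares of susceptible H3K27me2 sites ranged from -1.1 to -0.51 points (promoter; passing without susceptible 53), -4.75 to -0.52 (gene body; passing without control 52) and 1.03 to 5.75 (intergenic; passing without either). ELS shares ranged from 0.92 (without control 37, not passing) to 2.38 (promoter), -8.43 to 2.9 (gene body; 2.9 without ELS library 48, 0.45 without control 37, both reversed) and -4.16 to 7.21 (intergenic; -4.16, -1.47 and -1.37 without ELS libraries 48 and 44 and control 37, reversed).

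For members with a site, promoter sites alone left 0 members in susceptible medium spiny neuron, synaptic adhesion, developmental, vascular and cortical lists, 0 in resilient synaptic adhesion, Polycomb and developmental lists and 3 in the resilient chemosensory list, and 0 in ELS synaptic adhesion and developmental lists and 8 in the chemosensory list; none passed, since few promoters hold sites, and the synaptic adhesion and Polycomb excess turned to a deficit. Adding intergenic sites by nearest gene gave 4 susceptible medium spiny neuron, 11 resilient Polycomb, 41 ELS synaptic adhesion, 8 ELS developmental and 143 ELS chemosensory members, none passing. It also gave 12 resilient H3K27me2 axon guidance members, a new excess, where the main test had 2 members against 2.03 expected and no call. Lists not matched on length ended the susceptible medium spiny neuron (3), vascular (0) and cortical (0) calls, and turned the susceptible axon guidance (14) and resilient potassium channel (11) and axon guidance (12) members from fewer to more than expected. At an adjusted p under 0.01 ELS synaptic adhesion (29), developmental (0) and chemosensory (14) members did not pass.

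For list directions, intergenic sites ended the resilient stress (80%), susceptible H3K27me2 synaptic adhesion (75.2%) and ELS Polycomb (30.8%) calls. Promoter sites ended the resilient chemosensory call (100%), and an adjusted p under 0.01 the ELS Polycomb call (20%). Over all results, 13 values of main results and 56 of the others newly passed under an alternative, and not all of these are listed here. With genes as units, matched on length or on length and GC alike, susceptible shares were 58.3% for potassium and 56.5% for sodium and calcium channels, both reversed, 79.5% for glutamate, 90.5% for GABA, 83.1% for synaptic adhesion, 83.5% for axon guidance and 25% for Polycomb genes, none passing. Resilient shares were 73.2% for potassium channels, 54.1% for glutamate (reversed), 67.5% for GABA, 67.3% for synaptic adhesion and 73.7% for axon guidance genes, and ELS shares 49.8% for synaptic adhesion and 25% for Polycomb genes, none passing.

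Without single libraries, shares ranged from 20% to 23.5% for susceptible Polycomb genes (lost without control 31) and stayed at 0.0% for Cx3cr1. Resilient shares ranged from 65% to 74.4% for potassium channels, 68.4% to 80.8% for GABA, 64.6% to 75.4% for axon guidance and 70% to 83.3% for stress genes. The susceptible H3K27me2 synaptic adhesion share stayed at 100%, and the ELS shares ranged from 34.3% to 66.7% for synaptic adhesion (66.7% without control 37, not passing) and 0.0% to 50% for Polycomb genes (0.0% without control 37, 50% without control 45). Genes shared by susceptible H3K27me1 and H3K27me2 passed when not matched on length (18 higher and 22 lower) or in promoters (13 lower), as did those higher in susceptible and ELS tables (429 not matched, 2 in promoters).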

Other observations

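All tests in this part were chosen after the data were seen.

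Several clustered regions went opposite ways in susceptible and resilient H3K27me1 libraries. Besides the chromosome 7 region from 20000001 to 25000000, a gene-poor stretch of chromosome 12 from 20000001 to 25000000, with 15 protein-coding genes, was one of them. There 8 of 141 susceptible sites (5.67%) and 42 of 66 resilient sites (63.6%) were higher (Fisher's exact test over sites, adjusted p = 3.33e-17). On chromosome 7 from 30000001 to 35000000, with 108 genes, 4 of 45 susceptible and 48 of 53 resilient sites were higher (8.89% and 90.6%; adjusted p = 7.84e-16). On chromosome 4 from 145000001 to 150000000, where 18 of 68 genes are zinc finger genes of the Zfp family, the shares were 29.6% of 98 and 79.4% of 68 sites (adjusted p = 7.84e-09). Among the vomeronasal receptor genes, Vmn1r139 had 3 of 3 resilient sites higher and 2 of 3 susceptible sites higher, although its leading susceptible site was lower (230 ± 18 against 294 ± 30.1 reads, SD, n = 4).

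Gene length went with direction as well. In susceptible libraries the mean share of higher sites per gene was 10.4% in the shortest of 5 length classes of genes with a site (median length 12.2 kb) and 64% in the longest (median 239 kb), and in resilient libraries 26.6% and 60.4%, whereas in the ELS comparison the mean shares per gene were 70.2% and 66.6%. Genes with many sites in the ELS table were Pcdh15, an adhesion gene of sensory hair cells, with 20 sites (16 higher), and Dmd, the dystrophin gene, with 18 (7 higher).

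Sites on the sex chromosomes appeared in the ELS table alone, with 335 on X and 505 on Y among those that passed. The 4 defeat tables held 0 on either, and 3 to 5 on the mitochondrial chromosome. Whether windows on X and Y were tested in the defeat cohort was not established, so these counts do not show a change particular to ELS.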
